A study of Mus musculus with 9 samples.

How the data were processed

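The study prepared cells from deep cervical, superficial cervical and inguinal lymph nodes of female WT and 5xFAD mice aged 10 to 11 months. Per the labels' protocols, nodes were digested with an enzyme mix, cells were stained with 1 of 4 hashtag antibodies, only suspensions with a viability above 87% were used, and cells were combined in equal numbers. The protocol text used here breaks off before it says which units were made equal, so equal shares of the identities within a library are an assumption of the goodness-of-fit tests. Gene expression, immune receptor and surface protein libraries were then made with a droplet-based kit that reads the 5' end of transcripts. The submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.1.0 and the mm10 genome build. Which step each served, and how the authors called cells, assigned hashtags or removed doublets, is not given in the sources used here.

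The deposited files are text lists with 1 row per cell barcode. Per the file headers, those of the 6 single-node libraries give a barcode, an identity (a number, or the name no.ab) and a condition, which is a node type with wt or ad. Those of the CD4 lists and the mixed library give a barcode, an animal and a node type with WT or AD. The lists were made by the authors and carry names only: no read depth, UMI number or expression value per cell. AD was read as 5xFAD because every row of the 3 single-node samples labelled 5xFAD carries it. Whether the identity numbers 1 to 4 stand for mice or for hashtags is not given, so an identity is treated as 1 suspension of cells and takes the place of the animal in the tests. Where nothing says that identities are separate animals, p-values measure only the spread between these suspensions. No identity named as a doublet appears in the lists, and no doublet caller was run, since it needs expression. How cells labelled CD4 were obtained is not given in the sources used here.

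Samples were grouped by their labels into 9 groups of 1 library. The labels put 1 CD4 list under WT and the other under 5xFAD, whereas both files name animals of both genotypes. Genotype within these lists was therefore taken from the file, row by row, and the lists were not compared as groups. Their counts were averaged by partner animal because they hold nearly the same barcodes.

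The number of cells stands for depth here. Library totals have exact Poisson intervals and shares have exact Clopper-Pearson intervals at the 95% level, and a count of 0 is given the limit of 3 counts over the total. Equality of shares within a library was tested with a chi-square goodness-of-fit test, which speaks of the cells of that library only. Cells per identity were compared between genotypes and node types with exact two-sided permutation tests, per node type and stratified, with Benjamini-Hochberg adjustment over the 3 node types or the 3 pairs of node types, and chi-square p-values were adjusted over the 9 lists. The test between node types permuted all identities of both node types, without strata. The test of whether the genotype difference varied with node type permuted node labels within genotype, so its spread also holds any difference between node types that both genotypes share. Cell numbers after pooling measure loading, capture and filtering of a suspension, not the size of a node. Shared barcodes were compared with the product of list sizes over 737280, the number of barcodes that the kit allows, by an exact binomial test with adjustment over 36 pairs. The 28 pairs without the second CD4 list imply a pool of 718044 barcodes from the data themselves. On simulated lists the overlap test called 5.5% of 200 unrelated pairs and 100% of 200 pairs with planted copies. The stratified permutation test called 5.8% of 500 simulated comparisons without a difference. Those comparisons used independent identities, whereas in the data identities of one genotype and node type shared a library. The 5.8% therefore does not cover the p-values given for such identities.

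The intervals, the test of equal shares, the tests of cells per identity between genotypes and between node types, and the tests of shared barcodes and of their identities were fixed before the data were examined. The comparison of no.ab shares between genotypes by exact sign flips, the test of whether the genotype difference varied with node type, the averaging of the CD4 lists and the genotype of their animals as the lists name it were chosen after the data were seen. Alternatives fixed beforehand were counting each barcode once, leaving out barcodes found in another list or cells without a numbered identity, another denominator, the ratio of largest to smallest identity, shares or log2 values (pseudocount 1) in place of cell numbers, leaving out each identity in turn, a block on the identity number, barcodes with their suffix, the union of listed barcodes as the pool, and chance from products of shares. The rule for naming items was to report every library, node type and animal that the lists name. The rule for naming genes and the list of cell type markers could not be applied, because the lists hold no genes, and the planned gene comparisons were not run. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.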

Results

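Single immune cells were prepared from 3 types of lymph node of female wild-type (WT) and 5xFAD mice aged 10 to 11 months. 5xFAD mice are a transgenic model of Alzheimer's disease that develops amyloid plaques in the brain. The deep cervical lymph nodes (dCLN) receive drainage from the brain and its meninges, the superficial cervical nodes (sCLN) receive drainage mainly from the head and face, and the inguinal nodes (iLN) drain skin away from the head. Cell suspensions were marked with antibody-borne oligonucleotides (hashtags) before they were combined and captured on a droplet platform. The data used here are the lists that give each retained cell barcode its node type, genotype and numbered identity or animal. The lists hold no gene, receptor or surface protein values, so expression and cell type composition were not analysed here. The comparisons below therefore concern how many cells each node, genotype and animal contributed, and whether the lists describe separate cells.

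The lists held 69870 rows. Of these, 46176 belonged to 6 single-node libraries, with 1 library for each node type and genotype, and the rest to 2 lists labelled CD4 from deep cervical nodes and 1 mixed library of all 3 node types. Among the single-node libraries the deep cervical 5xFAD library was the largest, with 10156 cells (95% exact Poisson interval 9959 to 10356), and the inguinal WT library the smallest, with 6213 cells (6059 to 6369). The deep cervical WT library held 7844 cells, the superficial WT library 7451, the superficial 5xFAD library 6873 and the inguinal 5xFAD library 7639. The CD4 lists held 7818 and 7814 cells and the mixed library 8062. Each group had 1 library, so library totals had no replicate and the intervals cover counting error only.

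In the 6 single-node libraries the node type and genotype written beside every cell were those of the sample label. The CD4 lists departed from their labels. The list labelled WT named 3692 of its 7818 cells (47.2%) as 5xFAD, and the list labelled 5xFAD named 4117 of its 7814 cells (52.7%) as WT. Both CD4 lists thus contained cells of both genotypes, from 2 WT and 2 5xFAD animals each, and genotypes in these lists are given below as the lists name them. The mixed library, labelled with both genotypes and all node types, contained inguinal, superficial and deep cervical cells of 5xFAD, each named animal 1, and deep cervical cells of WT, named animal 2. No superficial or inguinal WT cells were among its 8062 cells.

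The first comparison asked whether 5xFAD nodes contributed more or fewer cells per identity than WT nodes of the same type. In the deep cervical libraries the 3 5xFAD identities held 3267 ± 110 cells (SD, n = 3) and the 3 WT identities 2330 ± 179 cells (SD, n = 3), a ratio of 1.40. The inguinal libraries went the same way, with 2448 ± 182 cells per 5xFAD identity and 2010 ± 112 per WT identity, a ratio of 1.22. In both node types every 5xFAD identity exceeded every WT identity. In the superficial libraries the means were 2254 ± 90.3 for 5xFAD and 2318 ± 197 for WT, a ratio of 0.97, and the ranges overlapped.

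With 3 identities per genotype the exact two-sided permutation test cannot give a p below 0.1. It gave p = 0.1 for the deep cervical and inguinal nodes and p = 0.7 for the superficial nodes (Benjamini-Hochberg adjusted exact p = 0.15, 0.15 and 0.7). Pooled over node types, with node type as a stratum, the 5xFAD mean exceeded the WT mean by 437 cells per identity (exact permutation p = 0.007 over 8000 regroupings, n = 9 identities per genotype). Identities of one genotype and node type came from 1 library, so this p treats identities captured together as independent. With the library as the replicate, the mean difference was 1053 cells per library (exact sign-flip p = 0.5, n = 3 node types). These totals count all listed cells, those named no.ab included, whereas the numbers per identity leave them out. The smallest possible p of that test is 0.25, so it could not pass the threshold. Without the deep cervical libraries the pooled difference was 187 cells per identity (exact permutation p = 0.14, n = 6). The difference between genotypes was not shown to vary with node type at the adjusted threshold. The test permuted node labels within genotype, so the gap between deep and superficial 5xFAD identities entered its own spread. It too treated identities that shared a library as independent. Unequal loading or recovery of single libraries could therefore give such contrasts, and their p-values cannot separate it from genotype. The superficial minus the inguinal contrast was -501 cells per identity (exact permutation p = 0.02, adjusted exact p = 0.06), the deep minus the superficial contrast 1000 cells (exact permutation p = 0.06, adjusted exact p = 0.09), and the deep minus the inguinal contrast 499 cells (exact permutation and adjusted p = 0.245).

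**Figure D1:**
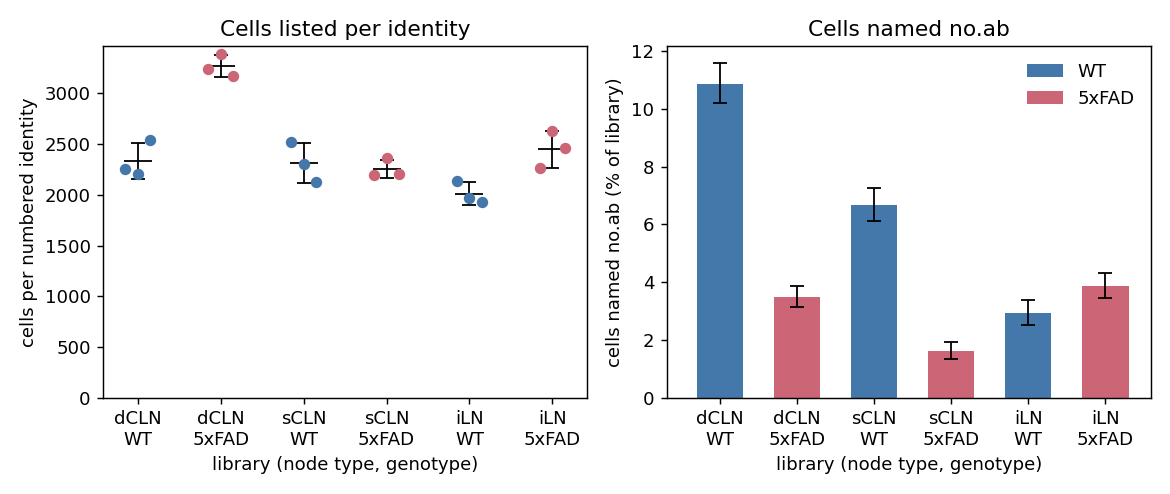
Left, cells listed for each numbered identity of the 6 single-node libraries (points; bar and whiskers, mean and SD of 3 identities). Right, cells named no.ab as a percentage of each library (whiskers, 95% exact binomial interval). The deep cervical 5xFAD identities lie between 3172 and 3388 cells, above all other identities, and the no.ab share is highest in the deep cervical WT library at 10.9%.

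Where both genotypes were captured together, the deep cervical difference did not have the same sign. These numbers compare samples within 1 library, and those of the CD4 lists concern cells labelled CD4. They are therefore not the same measure as cells per identity in separate libraries. In the mixed library the deep cervical 5xFAD sample held 1575 cells and the deep cervical WT sample 1864, a ratio of 0.84 with 1 animal each and no test. In the CD4 lists, counted as 1 library for the reason given below, the 2 5xFAD animals held 1632 and 2063 cells and the 2 WT animals 2060 and 2062 cells (means of both lists). The ratio of means was 0.90, and the exact permutation test gave p = 1 where the smallest possible p was 0.33. The difference rested on 1 animal: without the 5xFAD animal named deep_3 in the first list, 5xFAD exceeded WT by 2.25 cells.

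The second comparison was between node types, averaged over both genotypes. Deep cervical identities held 2799 cells on average and inguinal identities 2229, a difference of 569.5 (exact two-sided permutation p = 0.054, adjusted exact p = 0.094, n = 6 identities per node type). Deep and superficial identities differed by 513 cells (exact permutation p = 0.063, adjusted exact p = 0.094), and superficial and inguinal identities by 56.7 cells (exact permutation p = 0.65). The deep to superficial difference lay in 5xFAD (3267 against 2254 cells) and hardly in WT (2330 against 2318). The deep to inguinal means were 3267 against 2448 cells in 5xFAD and 2330 against 2010 in WT. None of these averaged differences between node types passed the threshold. With permutations kept within genotype, a test added after the data were seen, the deep to inguinal difference did so (adjusted exact permutation p = 0.015). Both deep cervical differences also passed without deep cervical WT identity 1 (622 cells to superficial and 678 to inguinal, adjusted exact permutation p = 0.045) and without identity 2 (632 and 689 cells, adjusted exact permutation p = 0.039). Those tests pooled the genotypes, so leaving out a WT identity weighted the deep cervical mean toward 5xFAD. The passes therefore hold part of the genotype difference and not node type alone. The same limit applies as for genotype, since identities of one node type and genotype shared a library. The mixed library, with 1 5xFAD sample per node type, gave another order. It held 2382 inguinal and 2241 superficial cells against 1575 deep cervical cells, so inguinal cells were 1.51 times the deep cervical cells. In the separate 5xFAD libraries the mean inguinal identity was 0.75 times the mean deep cervical identity. The first ratio compares samples within 1 library and the second compares libraries, so these are unlike measures and neither order decides the other.

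The labels' protocols speak of composite samples with equal cell numbers, but the text used here breaks off before it says of what. Equal shares of the numbered identities or animals of each library were taken as the reference on that assumption. Departures from equal shares exceeded counting error in all 9 lists (chi-square goodness of fit, adjusted p from 4.8e-42 in the mixed library to 0.027 in the deep and superficial 5xFAD libraries). The CD4 lists hold nearly the same barcodes, so their results are not separate, although both entered the adjustment. Without barcodes found in another list, the superficial 5xFAD library no longer passed the test, with a coefficient of variation of 3.76% against 4.01% with all cells. The departures were small in the single-node libraries, where the coefficient of variation over 3 identities ran from 3.38% in the deep cervical 5xFAD library to 8.50% in the superficial WT library. It was 11.0% over the 4 animals of either CD4 list and 18.2% in the mixed library. In the CD4 lists 3 animals each supplied about 26.4% of the cells, and the remaining 5xFAD animal supplied 20.9% (95% exact binomial interval 20.0 to 21.8% in the first list).

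Each single-node library also contained cells named no.ab in place of a number, a name that the labels do not define. Their share was 10.9% (95% exact binomial interval 10.2 to 11.6%) in deep cervical WT, 3.50% (3.15 to 3.87%) in deep cervical 5xFAD, 6.68% (6.13 to 7.27%) in superficial WT and 1.62% (1.33 to 1.94%) in superficial 5xFAD. In the inguinal libraries it was 2.93% (2.52 to 3.38%) in WT and 3.86% (3.44 to 4.32%) in 5xFAD. The WT share thus exceeded the 5xFAD share by 7.38 percentage points in deep and 5.07 points in superficial cervical nodes, and the WT minus 5xFAD difference in inguinal nodes was -0.93 points. Over the 3 node types the share was 6.83 ± 3.97% in WT and 2.99 ± 1.21% in 5xFAD (SD, n = 3 libraries each, exact sign-flip p = 0.5, smallest possible p 0.25). The CD4 lists and the mixed library had 0 such cells, a counting limit of 0.038% and 0.037% of the listed cells. Whether such cells were removed before these lists were made is not given, so the limit does not cover the captured cells.

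The last comparison asked whether the lists describe separate cells. Independent captures should share barcodes only by chance, and 28 pairs of lists, those without the second CD4 list, did so. They shared between 55 and 125 barcodes each, 2340 in total against 2279 expected, and none of the 28 departed from chance (exact binomial test, lowest unadjusted p = 0.11, lowest adjusted p = 0.79). The CD4 lists shared 7809 barcodes against 82.9 expected, which is 99.9% of each list. Only 9 barcodes of the first list and 5 of the second were missing from the other.

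The animals named for these shared barcodes corresponded one to one. Cells of deep_1, deep_2, deep_3 and deep_4 in the first list were named deep_5, deep_6, deep_7 and deep_8 in the second for 7796 of 7809 barcodes (99.8%, 95% exact binomial interval 99.7 to 99.9%). Permuting the names gave 25.2% on average and at most 27.1% in 10000 draws (p = 0.0001, permutation test, the smallest these draws can give). Of the 13 barcodes with another partner, 8 also changed genotype. Because of these shared barcodes the CD4 lists were counted as 1 library of 4 animals. The cell numbers of partner animals, such as 2061 and 2058 for deep_1 and deep_5, differed by less than sampling noise, which follows from the shared barcodes.

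**Figure D2:**
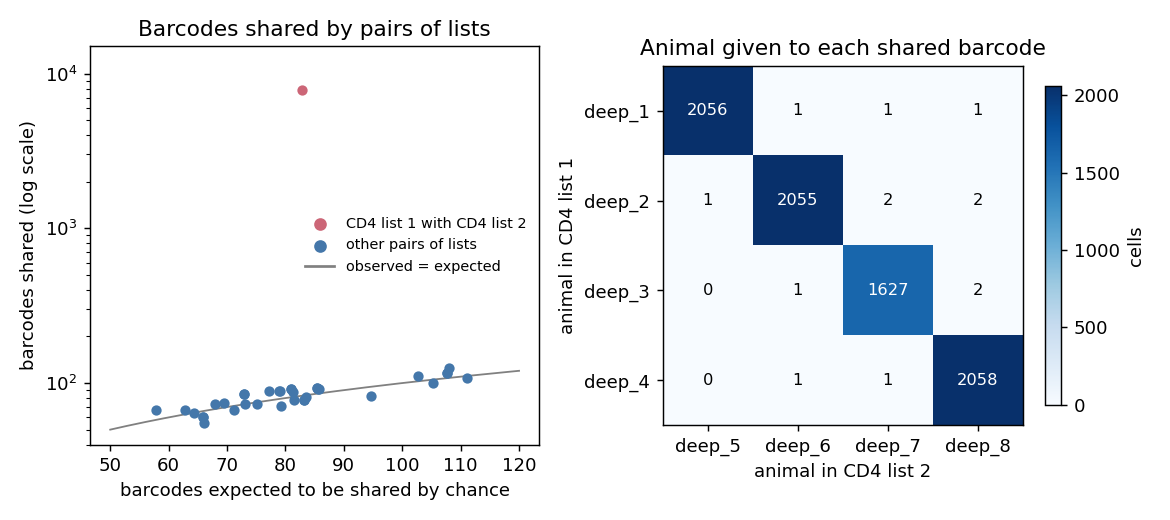
Left, barcodes shared by each of the 36 pairs of lists (log scale) against the number expected by chance, with the line of equality. Right, number of shared barcodes for each combination of animal names in the CD4 lists. The pair of CD4 lists shares 7809 barcodes where 82.9 were expected, and the diagonal of the matrix holds 7796 of them.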

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

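The numbers of shared barcodes and of their one-to-one names come from tests fixed before the data were examined, and the 1-base and other-list tests of the no.ab cells were set before their outcome was known. The bounds applied to the CD4 lists and the other tests in this part were chosen after the result was seen.

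The CD4 lists held nearly the same barcodes. Chance sharing is argued against by a number of shared barcodes 94.2 times the expectation. Partial swapping of reads between separate wells would leave most barcodes in 1 list only, and at most 0.115% of a list was missing from the other. That both lists describe the same cells of 4 animals, named in different ways, is consistent with the one-to-one naming of 99.8% of shared barcodes. Whether the same library was sequenced or assigned more than once, or whether 1 list was deposited in place of another, stays open, and no biological explanation was tested.

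The share of no.ab cells differed between WT and 5xFAD in opposite directions by node type: 7.38 points in deep cervical and 5.07 points in superficial nodes, against -0.93 points (WT minus 5xFAD) in inguinal nodes. With 1 library per group this difference of directions was not tested. An unhashed sample of equal cell number is argued against, since no.ab cells reached at most 0.366 of the mean numbered identity. Carry-over from the other single-node libraries is argued against too, since the share of no.ab barcodes found in another of these lists exceeded that of numbered cells by only 0.453 points (95% interval -0.44 to 1.49). No no.ab cell can be a barcode copy 1 base away from a listed hashed cell (difference 0), a property of all listed barcodes, of which 0 of 59763 had such a neighbour where random sequences would give 20.0 pairs, while genotype (exact sign-flip p = 0.5) and uneven staining of a suspension stay open.

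The deep cervical and inguinal libraries held more cells per 5xFAD than per WT identity. In deep cervical nodes, WT cells named no.ab cannot be the whole cause, since the ratio of all listed cells was still 1.29. In inguinal nodes they cannot explain the difference, since no.ab cells were fewer in WT (182) than in 5xFAD (295). The ratio of all listed cells was 1.23 there (95% counting interval 1.19 to 1.27), and 0.92 (0.89 to 0.95) in superficial nodes. Genotype and the number of cells loaded or recovered per library cannot be told apart in the single-node libraries, because each genotype and node type had a library of its own. The intraclass correlation of identities within these libraries was 0.887, which both explanations predict. In the mixed library, where both genotypes shared a capture, the deep cervical 5xFAD to WT ratio was 0.845, from 1 animal each.

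Among the 4 animals of the CD4 library, the 5xFAD animal named deep_3 in the first list held 1631.5 cells (mean of both lists), far from the others at 2059.5 to 2063 over both genotypes. Its gap to the nearest animal was 0.992 of the range, and chance passes the 95% limit of this criterion in about 5% of groups. In the first list the other animals supplied between 26.36 and 26.41% of the cells. These shares lie closer together than counting error, since the 95% exact binomial interval for deep_1 was 25.4 to 27.4%. Such closeness raises the gap as a part of the range, and its cause was not tested.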

How the results depend on the processing

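The options without the deep cervical libraries, with library totals, with genotype as a stratum of the node type test, with single CD4 lists, with no.ab cells added to identities and with the pool implied by other pairs were chosen after the data were seen. Leaving out barcodes found in another list left 7278 and 9444 cells in deep cervical WT and 5xFAD, 6886 and 6370 in superficial, 5747 and 7076 in inguinal, 9 and 5 in the CD4 lists and 7476 in the mixed library, too few CD4 cells for shares or tests. It also ended the call of unequal shares in superficial 5xFAD, with a coefficient of variation of 3.76% against 4.01%; the cause was not tested. Without no.ab cells the totals were 6991 and 9801 in deep cervical WT and 5xFAD, 6953 in superficial WT, and 6031 and 7344 in inguinal. Of the shares of cells, 82 values stayed within their intervals and 12 left them when no.ab cells were taken out of the denominator. Many of the 82 could not change, because each barcode was already listed once per library. The CD4 and mixed lists also held no no.ab cells to take out. The pooled genotype difference kept its sign in every alternative run, but its exact p rose above 0.05 with shares (1.28 points, permutation p = 0.19), without the deep cervical libraries (187 cells) and with library totals (1053 cells, 3 pairs). As shares of a library, which the no.ab share fixes by construction, the superficial difference reversed to 1.69 points and the inguinal to -0.31 points. Leaving out identities gave -157.5 to 39 cells in superficial nodes (39 without WT identity 2) and -429 to 2.25 cells in the CD4 library (2.25 without deep_3). The deep minus superficial difference then ran from 395 to 632 cells and the deep minus inguinal from 452 to 689, and both passed the adjusted threshold without deep cervical WT identity 1 (622 and 678) or 2 (632 and 689). The superficial minus inguinal difference ran from -3.77 to 136 cells, below 0 without inguinal WT identity 4. With genotype as a stratum the deep minus inguinal difference of 569.5 cells passed, since the genotype difference no longer entered its spread. A replicate block on identity numbers changed no call and gave 480, 469.5 and 61 cells for deep minus superficial, deep minus inguinal and superficial minus inguinal. With 4 pairs each its exact p cannot fall below 0.125, so it says nothing about stability, and 4 of 12 same-numbered pairs deviated the same way, so the numbers were not taken to pair the suspensions. With the union of listed barcodes as the pool, the other pairs shared 0.083 of expectation, a reversal that follows from a pool made of the lists themselves, while the CD4 lists shared 7.64 times the expected number. The comparisons of genes and cell types were not run, as the lists hold no expression.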

Other observations

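Each single-node library listed 3 of the identity numbers 1 to 4, although 4 hashtags were in use. The number 4 was absent from both deep cervical libraries and the number 1 from both superficial libraries. In the inguinal nodes the number 3 was absent from the WT library and the number 2 from the 5xFAD library. In the same libraries the cells named no.ab were 853, 355, 498, 111, 182 and 295 in deep cervical WT and 5xFAD, superficial WT and 5xFAD, and inguinal WT and 5xFAD. The CD4 lists and the mixed library listed 4 identities each and no such cells.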
